A study of Mus musculus with 24 samples.

How the data were processed

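Liver RNA of 18 male C57BL6J mice was measured on Affymetrix 3' in vitro transcription arrays, 1 array per mouse. Per the labels, 6 mice received a low-fat diet (LF), 6 a high-fat diet with 45% fat (HF) and 6 the same high-fat diet with 5% powdered propagules of Japanese yam (HF+P). Mouse numbers recur between the groups; the labels state no pairing, and each label was treated as a separate animal. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated amplified RNA was hybridised.

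The deposited value table holds 45101 probe sets and 24 columns, because the 6 HF arrays were processed with the LF arrays and again with the HF+P arrays, per the series' design text. The 2 resulting value sets of 12 columns were never mixed in a test. Per the submitters' processing notes, R 2.7.2 was used; the summarisation method, the normalisation and the log base are not given in the sources used here. The values deposited by the authors lie between 5.36 and 15.0 in every column and were handled as log2 values, since this is the range of log2 array intensities. Column medians were 6.90 in the set of LF and HF and 6.85 in the set of HF and HF+P.

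Differences between the arrays are very small for most probe sets. The SD over the 12 columns had a median of 4.17e-06 in the first value set and 4.27e-06 in the second, with highest values of 0.319 and 0.201. A difference in these values is therefore not a fold change, and none is given. The size of a change is given as the standardized difference, the difference of the group means divided by the pooled within-group SD, with the small-sample correction of Hedges for 10 degrees of freedom and a 95% interval from the noncentral t distribution. Where largest changes were picked, differences of the deposited values were ranked, as fixed beforehand, which favours probe sets with a wide spread.

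Probe sets were named through the platform annotation. A single gene symbol was listed for 34958 probe sets, several for 932, and 9211 were not listed; probe sets with several symbols or none were not named. Of the named probe sets, 34754 matched a gene identifier of the RefSeq table of GRCm38.p6, which changed 0 symbols. Each of the 18194 genes was represented by the probe set with the highest mean over all 24 columns. For 9182 genes there was only 1 probe set, and the most for a gene was 12.

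Each comparison was fitted in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 6 mice per group and no covariate, two-sided, with Benjamini-Hochberg adjustment over the 18194 genes and a threshold of 0.05. The prior degrees of freedom were 0.654 for HF against LF and 0.696 for HF+P against HF, so that genes borrowed little from each other's spread. The number of arrays, 6 per group, limits the precision.

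A set of 35 gene lists of pathways, liver zones and cell types was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; 657 of the 736 listed entries were measured, 7 to 34 per list, and 30 genes stood in more than 1 list. The lists covered cholesterol synthesis, sterol regulation and uptake, fatty acid synthesis, PPAR-alpha targets and fatty acid oxidation, lipid droplets, apolipoproteins, bile acids, gluconeogenesis, glycolysis, amino acid catabolism, xenobiotic P450 enzymes, NRF2 targets, acute phase, interferon response, MHC class II, unfolded protein response, heat shock, circadian clock, cell cycle, oxidative phosphorylation, ribosomal proteins, sex-biased genes, liver zonation, and markers of hepatocytes, macrophages, lymphocytes, neutrophils, stellate, endothelial, bile duct, red blood, pancreatic acinar and fat cells. In addition, a score per mouse was computed as the mean over a list's members of the value minus the HF mean, in pooled SDs, and compared by an exact two-sided permutation test over all 924 assignments of 12 mice, adjusted over the 35 lists. The test is exact only in that every assignment was counted. The pooled SDs came from the real groups and were not recomputed per assignment, which can favour the real one.

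The groups, tests, lists, other settings to try and the rule for naming genes were fixed before the data were examined. The named genes were the 8 largest rises and the 8 largest falls among genes past the threshold, up to 3 members past the threshold per list, 15 genes of liver lipid and glucose metabolism of which 13 were matched and analysed, and genes called in both comparisons, 51 genes in all. The permutation test of list scores, the standardized differences, a rescaling of values and median centring for named genes and lists were chosen after the data were seen. The settings fixed beforehand were quantile normalisation, centring on column medians, leaving out the dimmer part of the genes, other ways of representing genes, limma with trend and robust settings, array weights, rank products, a 1.5-fold minimum, a looser threshold, the mouse number as a block, and leaving out each mouse.

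On simulated data, drawn as normal noise with the mean and pooled SD of each gene, with 100 genes shifted by 3 SDs and 100 by 6 SDs among 18194, the fit recovered 59% and 99% for HF against LF, and called 9 genes that were not shifted. For HF+P against HF it recovered 56% and 99% and called 9 such genes. Since both comparisons use the same HF mice, values for their relation are given beside 100 simulations that combine the arrays' residuals at random with shared HF mice and no effect of the propagules, and with the HF mice split 3 and 3 in all 20 ways. For shares among called genes, these simulations kept the measured differences of HF and LF. For correlations, covariances and the overlap of calls they held no difference of HF and LF either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.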

Results

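Hepatic gene expression was compared between 6 mice on a low-fat diet (LF), 6 mice on a 45% high-fat diet (HF) and 6 mice on the high-fat diet containing 5% powder of propagules (HF+P), the small aerial tubers of Japanese yam. The diets lasted 4 weeks and the mice had fasted for 16 h when the livers were taken. Levels of 18194 genes were read from 1 array per mouse, so that precision rests on 6 arrays per group. Because the deposited values differ very little between arrays for most probe sets, and the SD of the same HF arrays differs between the value sets in which they were processed, sizes are standardized differences in units of the pooled within-group SD, and not fold changes.

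The comparison of HF with LF addressed the effect of high-fat loading. Genes of cholesterol synthesis were higher in HF livers: of the 17 measured members of this list, 16 rose, 0 fell and 1 did not pass, with a median standardized difference of 3.96. Msmo1, a C-4 methylsterol oxidase, rose by 10.1 pooled SDs (95% interval 5.61 to 14.6, n = 6 per group; limma, Benjamini-Hochberg adjusted p = 7.31e-06), from a deposited mean of 8.14 ± 0.019 in LF to 8.40 ± 0.028 in HF (SD, n = 6). Cyp51, the lanosterol demethylase, rose by 8.84 (4.88 to 12.8), and Idi1, isopentenyl diphosphate isomerase, by 7.80 (4.27 to 11.3). Sqle, squalene epoxidase, rose by 5.96 (3.17 to 8.71) and Fdps, farnesyl diphosphate synthase, by 5.91 (3.14 to 8.65), although another probe set of Fdps had the opposite sign (-1.03). In these 5 genes all 6 HF mice lay above all 6 LF mice. The list was called by limma's camera (adjusted p = 1.37e-35; adjusted p = 0.00367 with an estimated correlation), and adjusted over the list alone 16 members rose as well.

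Genes of sterol regulation and uptake moved with them in part. Of 12 measured members 3 rose and 0 fell; adjusted over the list alone 4 rose and 2 fell. Insig1, which retains the SREBP complex in the endoplasmic reticulum when sterols are abundant, rose by 4.65 (2.36 to 6.88). Stard4, a sterol transfer protein, rose by 4.25 (2.12 to 6.34) and Srebf2, the transcription factor of the cholesterol synthesis genes, by 2.85 (1.20 to 4.43). The deposited difference of Srebf2, 1.04e-05, is smaller than the shift of column medians between HF and LF, 3.36e-05. Its direction depends on the scaling, with -1.33 after median centring and -2.82 after quantile normalisation. Insig2, the related ER protein outside this list, fell by 2.68 (-4.21 to -1.09). The list was called upward (camera, adjusted p = 0.0349), with adjusted p = 0.142 with an estimated correlation, and was lost without HF mouse 2, 3 or 4 (adjusted p = 0.0506, 0.0542 and 0.104).

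**Figure D1:**
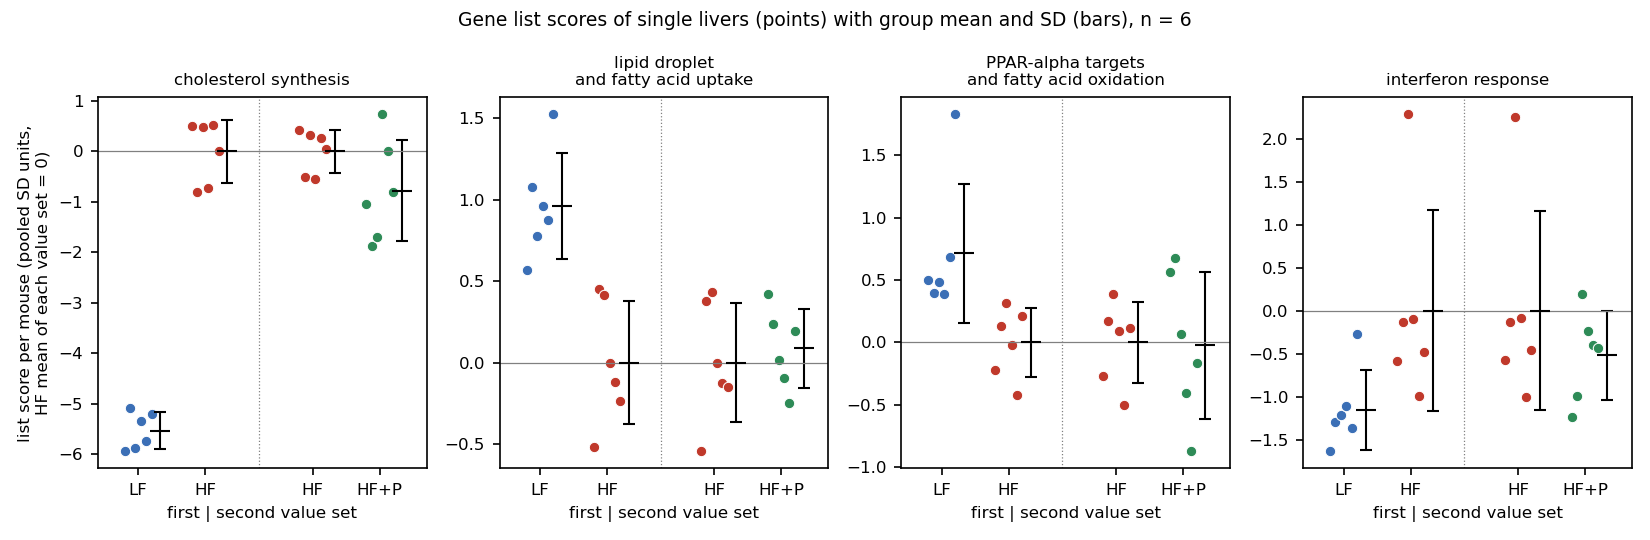
Scores of 4 gene lists in single livers (points; vertical axis in pooled SD units, with the HF mean of each value set at 0) and the mean and SD of 6 mice (bars), for LF and HF in the first value set and HF and HF+P in the second. The cholesterol synthesis score of all LF mice lies below that of all HF mice (difference 5.53), and HF mouse 3 has the highest interferon score (2.29).

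Several genes of fat use and storage fell in HF livers. In the list of PPAR-alpha targets and fatty acid oxidation, 5 of 34 measured members fell and 0 rose, among them Acot1, an acyl-CoA thioesterase, which fell by 3.42 (-5.21 to -1.59), Ehhadh, a peroxisomal oxidation enzyme, which fell by 3.08 (-4.74 to -1.36), and Pdk4, a kinase that inhibits pyruvate dehydrogenase, which fell by 2.38 (-3.82 to -0.885). The related copies of Acot1 make its assignment uncertain. In the lipid droplet and fatty acid uptake list 3 of 24 fell and 0 rose. Fabp2, a fatty acid binding protein, fell by 4.44 (-6.60 to -2.23), Cidec, a lipid droplet protein, fell by 3.97 (-5.95 to -1.94), and Mgll, monoacylglycerol lipase, fell by 2.45 (-3.91 to -0.933). Adjusted over the list alone, 8 members fell and 1 rose in the former and 7 fell in the latter. Camera called both downward (adjusted p = 0.0125 and 0.000614; adjusted p = 0.0555 and 0.105 with an estimated correlation). LF mouse 8 stood apart in the PPAR-alpha list, with a score of 1.83 against 0.39 to 0.69 in the other LF mice, and without it the call was lost (adjusted p = 0.197).

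Among apolipoproteins and lipoprotein handling genes, 2 of 18 fell, and 2 fell adjusted over the list alone. Apoc2, the cofactor of lipoprotein lipase, fell by 4.02 (-6.02 to -1.97) and Apoa4 fell by 3.23 (-4.94 to -1.46), and the list was not called (camera, adjusted p = 0.194). Another list test of limma, fry, called it downward (adjusted p = 0.0302). In the fatty acid synthesis list 2 of 26 rose and 2 fell, adjusted over the list alone 6 rose and 6 fell, and the list was not called (adjusted p = 0.762). Acss2, the cytosolic acetyl-CoA synthetase, rose by 2.62 (1.05 to 4.13), while Elovl5, an elongase of polyunsaturated fatty acids, fell by 2.86 (-4.45 to -1.21) and Acacb, an acetyl-CoA carboxylase, fell by 2.53 (-4.02 to -0.991). After quantile normalisation Acss2 had a value of -2.56, with ranks that spanned 3 places, so its direction depends on that setting. Genes followed whatever their result did not pass in several cases: Fasn had a standardized difference of 1.57 (0.293 to 2.78), Scd1 -1.38 (-2.56 to -0.154), Srebf1 0.047 (-0.999 to 1.09), Cpt1a -0.43 (-1.48 to 0.643), Cyp4a14 -2.03 (-3.36 to -0.635), Fgf21 -2.18 (-3.55 to -0.741) and Cyp7a1 -0.41 (-1.46 to 0.661). The values were -1.10 for Cd36, 0.87 for Pparg, -1.04 for Pck1 and -0.43 for Cidea, and the probe sets of Pck1 differed in sign.

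G6pc, the catalytic subunit of glucose-6-phosphatase, fell by 3.10 (-4.77 to -1.38) and was the 1 of 21 members of the gluconeogenesis and fasting list that changed; adjusted over the list alone 1 rose and 1 fell. Of 26 amino acid catabolism and urea cycle genes 0 passed over all genes, and 3 rose and 6 fell adjusted over the list alone. Camera called both lists downward (adjusted p = 0.0231 and 0.0150; adjusted p = 0.347 and 0.251 with an estimated correlation). The call of the gluconeogenesis list was lost without HF mouse 3 (adjusted p = 0.0676), LF mouse 3 (0.112) or LF mouse 5 (0.0507), and that of the amino acid list without LF mouse 3 (0.0619), LF mouse 5 (0.0515) or HF mouse 8 (0.0620). Of 17 cytosolic ribosomal protein genes 15 had lower values in HF and 0 passed, also when adjusted over the list alone. That list was called downward (adjusted p = 0.00348; adjusted p = 0.0555 with an estimated correlation). Among the array's 64 control probe sets, that of the murine B1 repeat was lower in HF (-2.70; limma, adjusted p over the controls = 0.0207), and those of 18S ribosomal RNA had values of -1.73, -1.26 and -1.23 that did not pass.

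Among xenobiotic enzymes 3 of 25 fell, adjusted over the list alone 1 rose and 4 fell, and the list was not called (adjusted p = 0.476; median 0.15, mean -0.52). Cyp3a11, the main CYP3A monooxygenase of mouse liver, fell by 9.24 (-13.3 to -5.11), Cyp3a44 fell by 4.67 (-6.92 to -2.38) and the carboxylesterase Ces2a fell by 3.45 (-5.25 to -1.61). The CYP3A genes are close copies that a probe set can share, which leaves their assignment uncertain. Of 31 NRF2 and glutathione genes 2 rose, and 2 rose and 1 fell adjusted over the list alone: Gss, glutathione synthetase, rose by 3.61 (1.70 to 5.45) and Sod2, the mitochondrial superoxide dismutase, by 2.49 (0.960 to 3.96). Their deposited differences, 1.08e-05 and 6.39e-06, are smaller than the shift of column medians between HF and LF, 3.36e-05. With median centring both had negative values (-1.30 and -1.65), so their direction depends on the scaling. The list was not called (adjusted p = 0.0929). Outside the lists, Enho, which encodes adropin, rose by 6.11 (3.26 to 8.93) and Osgin1 by 2.35 (0.862 to 3.77). Lepr, the leptin receptor, fell by 3.16 (-4.84 to -1.41), Tmem86a fell by 5.11 (-7.53 to -2.65) and the linker histone gene H1f2 fell by 3.55 (-5.37 to -1.67). Trim2 fell by 3.19 (-4.89 to -1.43), Tubb2a fell by 3.05 (-4.70 to -1.34) and Atf5 fell by 2.45 (-3.91 to -0.936). For Enho 1 of the 4 probe sets had the opposite sign.

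Immune lists and the unfolded protein response list lay higher in HF livers without any member passing over all genes; adjusted over the list alone 1 acute phase gene rose and 1 fell, and 0 passed in the others. Of 30 interferon response genes 29 had higher values in HF, with a median standardized difference of 1.08 (camera, adjusted p = 2.52e-09; adjusted p = 0.343 with an estimated correlation). All 18 lymphocyte and NK cell markers and all 7 MHC class II genes were higher, with medians of 0.71 and 0.94 (adjusted p = 0.00200 and 0.00705; adjusted p = 0.0555 and 0.347 with an estimated correlation). For 25 unfolded protein response genes the median was 0.89, for 27 acute phase and complement genes 0.45 and for 20 Kupffer cell and macrophage markers 0.65 (adjusted p = 0.000758, 0.0273 and 0.0421; adjusted p = 0.298, 0.298 and 0.570 with an estimated correlation). HF mouse 3 stood apart in this group of lists: its interferon score was 2.29, against values between -0.99 and -0.10 in the other HF mice. Its scores were also the highest HF values for MHC class II, macrophage (1.66) and lymphocyte markers (1.52). Without it the calls of the acute phase, Kupffer cell and pericentral lists were lost (adjusted p = 0.0590, 0.270 and 0.0923), and the score difference went from 1.15 to 0.695 for interferon, from 1.04 to 0.541 for MHC class II, from 0.787 to 0.483 for lymphocyte markers, from 0.435 to 0.263 for acute phase and from 0.460 to 0.129 for macrophage markers. Of 15 pericentral genes Gulo, an enzyme of vitamin C synthesis, rose by 2.97 (1.29 to 4.59). Adjusted over the list alone 5 rose, and the list was called upward (adjusted p = 0.0369; adjusted p = 0.347 with an estimated correlation).

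In all, 332 of 18194 genes were called, 124 higher and 208 lower in HF (limma, Benjamini-Hochberg), and camera called 14 of 35 lists, 9 upward and 5 downward. When the same 12 mice were split at random, camera called between 1 and 15 lists per split. A camera call of 1 list at the preset correlation is therefore weak evidence by itself. Cholesterol synthesis, sterol regulation, PPAR-alpha targets and lipid droplet genes also separated the groups in the exact permutation test of list scores (p = 0.00216 each, the smallest that 924 assignments can give; adjusted p = 0.0189), and 404 genes had groups that did not overlap, 2.22% of genes against 0.216% by chance. Of the 14 list calls only that of cholesterol synthesis held with an estimated correlation, 9 held without HF mouse 3, and 7 held in every fit without 1 mouse. Of 12 such fits, the Kupffer cell call was lost in 8, the pericentral call in 5, those of sterol regulation, gluconeogenesis, amino acid catabolism and acute phase in 3 each and that of PPAR-alpha targets in 1. With the mouse number as a block 261 genes were called, of which 160 were among the 332. Whether the calls depend on the scaling of the arrays could not be tested for most genes. Quantile normalisation gave 3345 genes, 131 higher and 3214 lower in HF, with 109 of the 332 among them. It sets values by rank, and the rank of a gene among 45101 probe sets spanned a median of 3 places over the 12 arrays. Of the 332 genes, 40 had the same rank in every array. Median centring gave 16089 genes, 231 higher and 15858 lower, with 275 of the 332. It shifted HF against LF by 3.36e-05, more than the difference of 90.6% of genes and of 134 of the 332. With these limits, no downward list call was kept in either setting. After quantile normalisation the lists of amino acid catabolism and of ribosomal proteins were called upward instead (camera, adjusted p = 0.00485 and 0.0239). Leaving out 1 mouse gave between 131 calls (without LF mouse 5) and 357 calls (without HF mouse 5), and at least 1 such fit lost the calls of 17 of the 40 named genes: Osgin1, Tubb2a, Insig2, Atf5, Srebf2, Elovl5, Acacb, Acss2, Ehhadh, Pdk4, Mgll, Ldha, Sod2, Susd4, Gulo, Tek and Serpinb6b.

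**Figure D2:**
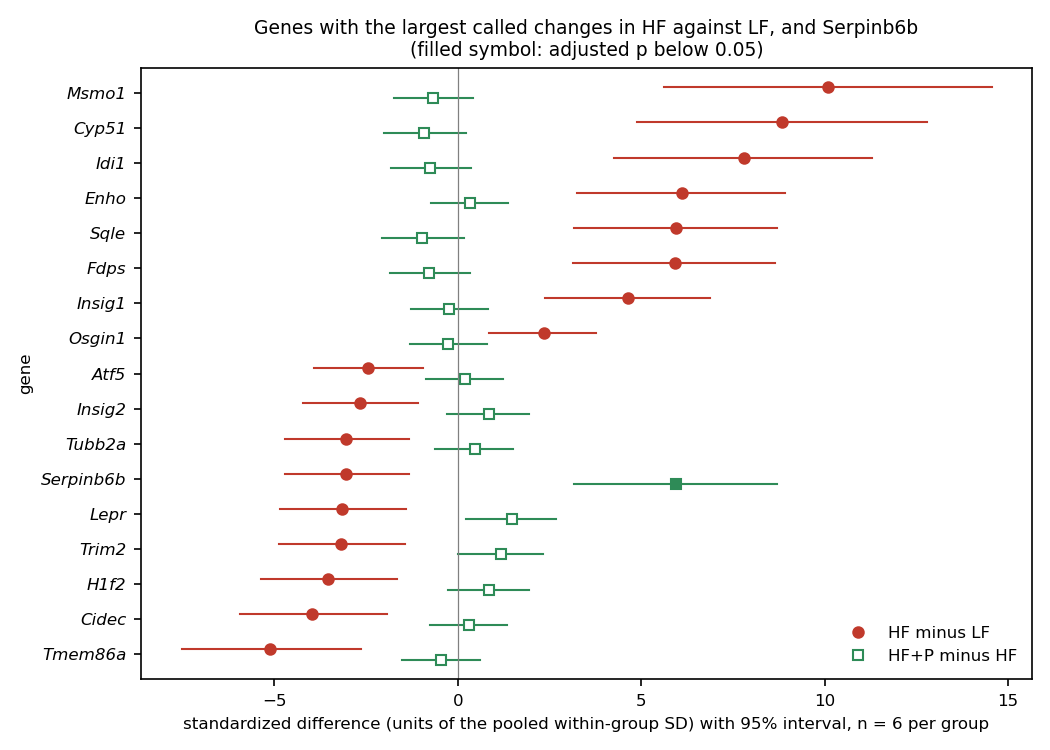
Standardized differences (horizontal axis, pooled SD units) with 95% intervals for selected genes called in HF against LF and for Serpinb6b, n = 6 mice per group. The genes were picked by the largest differences of deposited values, not by the plotted size. Circles give HF minus LF and squares HF+P minus HF, filled where the adjusted p passed; Serpinb6b is called in both comparisons, at -3.05 and 5.96.

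The comparison of HF+P with HF addressed the effect of ingesting the propagules. Serpinb6b, a member of the clade B serine protease inhibitors, was called higher in HF+P livers, by 5.96 pooled SDs (95% interval 3.17 to 8.72, n = 6 per group; limma, Benjamini-Hochberg adjusted p = 0.00402). All 6 HF+P mice lay above all 6 HF mice. The call rests on 1 probe set with a low level, a deposited mean of 6.975 in both groups where the column median was 6.85. The deposited difference was 0.000509. The gene had fallen by 3.05 (-4.70 to -1.34; adjusted p = 0.0179) in HF against LF, and it was the 1 gene called in this comparison; 1304 genes had an unadjusted p below 0.05, against 909.7 by chance. The call was lost after quantile normalisation, which could test this gene. Its rank spanned 12 places over the arrays of this comparison, against a median of 2 over genes. With the mouse number as a block it was not called in either comparison, and without HF mouse 4 the fall against LF was not called.

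Genes of cholesterol synthesis were lower in HF+P than in HF in 17 of 17 measured members, with a median standardized difference of -0.75, and 0 of them passed. Sqle had a value of -0.97 (-2.08 to 0.173), Cyp51 -0.91 (-2.01 to 0.223), Idi1 -0.75 (-1.83 to 0.357) and Msmo1 -0.68 (-1.75 to 0.419). Camera called the list downward (adjusted p = 0.000187), but not with an estimated correlation (adjusted p = 0.388) nor in the exact permutation test of the list score (difference -0.777, p = 0.113). The camera call was also lost after quantile normalisation (adjusted p = 0.149) and kept with median centring. The scores of 4 HF+P mice lay below every HF mouse, while the highest HF+P score, 0.736, lay above all of them.

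Other lists called downward by camera were interferon response (29 of 30 members lower, median -0.54), Kupffer cell and macrophage markers (18 of 20, -0.64), acute phase and complement (21 of 27, -0.39), lymphocyte and NK cell markers (15 of 18, -0.38) and pericentral genes (9 of 15, -0.28). Their adjusted p values were 0.000775, 0.00308, 0.00244, 0.0136 and 0.0428, and 0.637, 0.610, 0.296, 0.296 and 0.388 with an estimated correlation. Amino acid catabolism and urea cycle genes (20 of 26 members higher, median 0.52), gluconeogenesis and fasting genes (17 of 21, 0.46) and oxidative phosphorylation genes (20 of 26, 0.59) were called upward. Their adjusted p values were 0.00837, 0.0394 and 0.0394, and 0.388, 0.388 and 0.296 with an estimated correlation. No member of these lists passed over all genes, and adjusted over the list alone 0 members passed in each of them except pericentral genes, where 1 fell.

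The lists of PPAR-alpha targets and of lipid droplets gave camera no call here: the medians were -0.03 for PPAR-alpha targets and fatty acid oxidation and 0.01 for lipid droplet genes (adjusted p = 0.888 for each). Cyp4a14 had a value of 1.68 (0.378 to 2.92; adjusted p = 0.538), G6pc 1.45 (0.204 to 2.64) and Lepr 1.48 (0.227 to 2.68; adjusted p = 0.619), none of which passed. Fasn was at 0.20, Scd1 at -0.36, Srebf1 at -1.06, Cpt1a at -1.16, Cyp7a1 at -0.26, Cd36 at 0.12, Pparg at -0.41, Pck1 at 0.88, Fgf21 at 0.21 and Cidea at -0.71. The remaining 26 lists had camera adjusted p values between 0.0968 and 0.988, with 0 members passing over all genes. Adjusted over the list alone 2 male-biased genes fell and 0 members of the others passed. The median and the test differed in sign for apolipoproteins (median -0.17, called direction up), xenobiotic enzymes (median 0.21, down), pancreatic acinar markers (median 0.054, mean -0.029) and cholangiocyte markers (median 0.076, mean -0.0051). The camera calls of 9 lists came to 0 with an estimated correlation, with fry and in the permutation test, and to 2 without HF mouse 3; 7 of the 9 were lost without at least 1 mouse, all but cholesterol synthesis and acute phase. Without HF mouse 3 the score difference went from -0.520 to -0.0683 for interferon, from -0.538 to -0.191 for macrophage markers, from -0.511 to -0.223 for lymphocyte markers, from -0.528 to -0.341 for acute phase and from 0.482 to 0.294 for oxidative phosphorylation. Quantile normalisation kept 4 of the 9 calls and median centring 8, with the limits named above: ranks spanned a median of 2 places, and column medians differed by up to 6.66e-06, more than the SD of 65.8% of probe sets. HF mouse 3 had the highest interferon score in this value set as well (2.26).

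The relation between both comparisons was examined because they share the HF mice, with opposite signs. Of the 124 genes higher in HF than in LF, 105 (84.7%) were lower in HF+P than in HF, and of the 208 lower genes 172 (82.7%) were higher. In simulations with no effect of HF+P these shares averaged 66.5% (95% of simulations between 40.9% and 85.7%) and 63.7% (46.2% to 80.5%). These simulations took the measured differences of HF and LF as true, their chance part included, so the simulated shares can be too low. They cannot decide whether the measured shares exceed what the shared mice give. With 3 HF mice used to pick the genes and the other 3 for the comparison with HF+P, they averaged 63.5% and 67.2% over 20 splits. Over all 18194 genes, called or not, the signs were opposite in 68.3%, and in 55.8% on average with split HF mice. For correlations, covariance and overlap the simulations held no effect of the high-fat diet either. They are therefore no reference for an absent effect of the propagules alone. Across genes, which are not independent replicates, the correlation of the differences was -0.77 on the deposited scale, against -0.60 in the simulations (95% of them between -0.95 and 0.19) and -0.43 with split HF mice. For standardized differences it was -0.47, against -0.47 in the simulations (-0.77 to -0.16) and -0.21 with split HF mice. The covariance of the standardized differences was -0.334, against a simulated mean of -0.163 (95% of simulations between -0.457 and -0.0368) and -0.182 with split HF mice. The overlap of calls was 1 gene, Serpinb6b, against 0.0114 for independent lists in that pair of directions; 2 of 100 simulations had any overlap, too few for a stable simulated mean. Without HF mouse 3 the deposited correlation was -0.49.

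The 6 HF arrays could be compared between the value sets. Over 18194 genes, each mouse's deviations from the HF mean correlated with its own deviations in the other value set at 0.886 to 0.919, and the median correlation per gene over the 6 mice was 0.959. The SD of the same 6 arrays differed between the sets by a ratio from 0.265 to 3.81 (5th to 95th percentile of probe sets). LF and HF+P, which were processed apart, were set side by side through the HF mice, in units of the HF mice's SD within each value set and with no test. Serpinb6b lay 4.94 above the HF mean in LF and 5.04 above it in HF+P. This gene was picked for being called in both comparisons. A chance deviation of the shared HF mice can raise both values, so they do not show a return to the LF level. Msmo1 lay at -9.32 in LF and -1.23 in HF+P, Idi1 at -10.1 and -1.32, Sqle at -4.68 and -1.23, and Insig1 at -10.1 and -0.55. Among genes that had fallen, G6pc lay at 3.42 in LF and 1.81 in HF+P, Lepr at 7.08 and 2.96, and Cidec at 4.73 and 0.44. Of the 40 named genes called in HF against LF, 33 lay on the LF side of the HF mean in HF+P, a direction that the shared HF mice favour by themselves. The other 7 lay further from LF: Apoa4 (-1.66 in HF+P), Mgll (-0.78), Apoc2 (-0.58), Tmem86a (-0.50) and Fabp2 (-0.35), which had fallen, and Enho (0.42) and Srebf2 (0.24), which had risen.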

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

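The slope between the value sets, which replaced one computed with the same arrays on both sides, the tests of the interferon list and the permutation of list scores were chosen only after the result was seen.

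In groups of 6 mice, the distance of the highest or lowest mouse to its neighbour, divided by the range, was compared with the 95% critical value of Dixon's test, which chance exceeds in about 1 in 20 groups. Of 176 groups of values 16 exceeded it, where chance gives about 8.8. HF mouse 3 was the highest HF mouse in the scores of acute phase genes (ratio 0.790 with the LF comparison and 0.802 with the HF+P comparison), interferon response (0.727 and 0.720), lymphocyte and NK cell markers (0.666 and 0.647) and MHC class II (0.660). LF mouse 8 was the highest LF mouse for PPAR-alpha targets (0.795), Elovl5 (0.700) and Ldha (0.670). LF mouse 1 was lowest for sterol regulation (0.694) and LF mouse 3 highest for macrophage markers (0.632). Among HF mice, mouse 5 was highest for Apoa4 (0.741), mouse 8 highest for Acot1 (0.653) and mouse 4 lowest for Fasn (0.666). HF+P mouse 1 was highest for Cd36 (0.798).

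Probe sets without a single gene symbol were not part of the gene comparisons. Of 10092 such probe sets, counted without 51 of the array's controls, 25 passed in HF against LF (limma over all probe sets, Benjamini-Hochberg), 11 higher and 14 lower, and 0 in HF+P against HF.

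For the counts of calls, 100 of the 462 splits of the 12 mice into groups of 6 were drawn. In HF against LF, the real split was the 1 split with as many as 332 genes, and the highest of the others called 1, so that chance can be excluded at this level. For its 14 lists, 3 of 100 splits gave as many, the real one included, with 15 as the highest other. This share was not adjusted over the counts tested, so chance is not firmly excluded. In HF+P against HF, 3 of 100 splits called at least the 1 gene of the real split, the real one included, and the highest other count was 1. As for the 14 lists, this share was not adjusted over the counts tested, so chance is not firmly excluded. For its 9 lists, 32 of 100 splits gave as many and the highest other count was 17, so that chance cannot be excluded for the number of lists.

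The first pattern is the spread of the values: SDs between arrays ranged from 4.52e-09 to 0.319 over probe sets of the first value set. A candidate explanation is that the values were scaled by a factor of each probe set that differs between the value sets. The log ratio of the SDs of the same 6 HF arrays between the sets followed the log ratio of the LF mice's SD to the HF+P mice's SD, groups without HF mice, with a slope of 0.652 (SE 0.00165, R2 0.777), where values without such scaling should give a slope near 0; the explanation is not excluded. The ranking of deposited differences then favours the probe sets with a wide spread. No biological explanation was tested, since the arrays are the same.

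The second pattern is that camera called 9 lists in HF+P against HF and the exact permutation of mice called 0. Members of a list that vary together between mice beyond the preset correlation may produce this: the median estimated correlation of the called lists was 0.0980, above the preset 0.01, although it was -0.040 for oxidative phosphorylation and 0.020 for lymphocyte markers, which leaves the call of the former unexplained by it; the spread of these estimates was not tested. A single HF mouse apart from the others may contribute, since 2 of the 9 lists were still called without HF mouse 3. Both values came out as these explanations need, so neither is excluded for the lists as a whole. An effect of the propagules on some of these lists stays open and was not separated from them; the 2 lists still called without that mouse were cholesterol synthesis (adjusted p = 0.00139) and acute phase (adjusted p = 0.00754).

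The third pattern is the higher interferon response list in HF than in LF (score difference 1.15, exact permutation p = 0.0173; adjusted p = 0.0758). That HF mouse 3 alone carries it is argued against by the unadjusted test only: without it the difference was 0.695, with an exact permutation p = 0.0303, and 5 of 5 other HF mice lay above the LF mean, but adjusted over the lists p = 0.118. More macrophages in HF livers could also raise such a list; their marker score differed by 0.460 (95% interval -0.432 to 1.47, exact permutation p = 0.342), an interval that holds the interferon difference, so the tables leave this open. The brightest markers, Csf1r, Cd5l and Clec4f, had deposited LF means of 10.6, 10.3 and 9.85 and standardized differences of 0.54, 0.87 and 1.44; in all 16 of 20 markers were higher and 4 lower, among them Gpnmb at -1.71, and 0 of the 20 stood in another list. An effect of the diet on the interferon response remains open as well.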

How the results depend on the processing

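The rescaling, the permutation of list scores, median centring of named genes and lists, and the correlation of standardized differences were chosen after the data were seen; the other alternatives were planned. For HF against LF, 332 genes became 3345 with quantile normalisation (109 of them shared) and 16089 with median centring (275 shared). Column medians differ by up to 5.78e-05 in the first value set, more than the SD of 93.4% of probe sets, so centring moves most values by more than their spread. Quantile normalisation sets values by rank, and ranks of a gene spanned a median of 3 places over the 12 arrays; 48.4% of genes kept the sign of their difference. For most genes neither can tell whether the calls depend on the scaling. Leaving out the dimmer genes gave 502 calls, 290 of them shared (fewer genes tested), rescaling 597, rank products 1322, an adjusted p below 0.10 679 and a 1.5-fold minimum 0, which tests nothing, since the largest deposited difference was 0.364 and a 1.5-fold change is 0.585. The other 6 planned fits of these genes gave 261 to 345 calls. For HF+P against HF, 1 gene became 0 with quantile normalisation, without the dimmer genes (Serpinb6b is among those left out) and with a 1.5-fold minimum, 3 with rescaling and 738 with rank products. Rank products ranked deposited differences across genes, which favours probe sets with a wide spread, so their counts cannot be set against the others. The causes of the changes under rescaling and rank products were not tested.

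The mouse number as a block gave 261 genes for HF against LF, 160 of them shared with the fit without the block, and 0 for HF+P against HF, with 14 and 10 lists; Serpinb6b was not called in either. Same-numbered mice correlated at -0.13 to 0.14 and 0.05 to 0.20, over 0.1 in 3 of 6 and 1 of 5 pairs. Both mice of a number correlated best with each other in 4 of 6 pairs of HF and LF and in 1 of 5 of HF+P and HF. The labels state no pairing and the mice were not treated as pairs; a pairing of some HF and LF mice is not excluded.

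Called lists for HF against LF fell from 14 to 1 with an estimated correlation, 4 with fry and 4 by permutation; those for HF+P against HF went from 9 to 0, 0 and 0, and to 4 with quantile normalisation. The correlation of the comparisons was -0.502 (Spearman) and -0.471 (standardized); the overlap was 0 without the dimmer genes and with quantile normalisation. Cause not tested.

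Leaving out 1 mouse gave 131 to 357 genes for HF against LF: 168, 140, 131 and 197 without LF mice 1, 3, 5 and 8, and 194, 161, 178, 141 and 198 without HF mice 1, 2, 3, 4 and 8. It gave 9 (without HF mouse 3) to 14 lists. For HF+P against HF it gave 1 to 2 genes (2 without HF mouse 2 or HF+P mouse 8), Serpinb6b in all 12 fits, and 2 (without HF mouse 3) to 9 lists, with 5 without HF+P mouse 1. The correlation ranged from -0.799 to -0.494 (without HF mouse 3) and the overlap from 0 (without HF mouse 4) to 1. Of the 40 named genes called in HF against LF, 23 passed in all 12 of these fits and 0 changed sign.

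Quantile normalisation reversed 7 named genes in HF against LF: Srebf2 (-2.82), Acss2 (-2.56), Gss (-1.83), Sod2 (-0.53), Gulo (-0.53), Cyp3a11 (0.53) and Cyp3a44 (0.19). Sod2, Gulo and Cyp3a11 had the same rank in every array, so their values here are rounding error, and the ranks of the other 4 spanned 3 to 6 places. Median centring reversed Srebf2 (-1.33), Gss (-1.30) and Sod2 (-1.65), whose differences are smaller than the shift of 3.36e-05. The quantile reversals of Sod2, Gulo and Cyp3a11 say nothing about these genes. For Srebf2, Gss and Sod2 the called direction depends on the shift of the column medians, and which scaling is right was not tested. Acss2 and Cyp3a44 were reversed by quantile normalisation and not by median centring. Over the 6 other settings, 204 of 240 values of the called genes kept direction and side of the threshold, 26 lost the call and 10 reversed. Quantile normalisation gave 18 called lists and median centring 21 in HF against LF, all of them upward, with the same limits. The lists called downward without these settings were therefore not called downward in either. The number of arrays, 6 per group, limits what could be detected; signal over background is not given in the sources used here.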

Other observations

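No test below was chosen after its result was seen. Lists of other cell types and processes gave camera no call in HF against LF. Among markers of other cells, endothelial markers had a median of -0.53 with 1 of 17 called, Tek, the angiopoietin receptor, which fell by 2.53 (-4.02 to -0.992, n = 6 per group; limma, Benjamini-Hochberg adjusted p = 0.0402; list adjusted p = 0.111). Stellate cell and matrix markers (median 0.07), neutrophil markers (0.33), cholangiocyte markers (0.06, mean -0.07), red blood cell markers (0.13) and pancreatic acinar markers (-0.05, mean 0.22) had 0 members called; adjusted over the list alone 2 red blood cell genes rose and 1 fell, 1 acinar gene rose, and 1 endothelial gene rose and 2 fell. Their camera adjusted p values were 0.476, 0.174, 0.867, 0.497 and 0.497. Of 9 adipocyte markers 1 fell, Cidec, which the lipid droplet list also holds (adjusted p = 0.404; adjusted over the list alone 1 rose and 2 fell; median -0.065), and of 11 hepatocyte markers 0 were called (median -0.43, mean 0.11, adjusted p = 0.914).

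Among liver processes, Pigr, the polymeric immunoglobulin receptor, rose by 3.69 (1.76 to 5.57; limma, Benjamini-Hochberg adjusted p = 0.00737) as 1 of 12 periportal genes, a list that was not called (adjusted p = 0.711). Ldha, lactate dehydrogenase A, fell by 2.58 (-4.08 to -1.03; limma adjusted p = 0.0379) as 1 of 16 glycolysis and glycogen genes (list adjusted p = 0.0929; adjusted over the list alone 1 rose and 4 fell). Susd4 rose by 2.39 (0.891 to 3.83; limma adjusted p = 0.0474) as 1 of 14 male-biased genes, and Cyp3a44 fell as 1 of 12 female-biased genes (list adjusted p = 0.338 and 0.777; the female-biased median was 0.06 and mean -0.25). Adjusted over the list alone 1 periportal and 1 male-biased gene rose, and 1 female-biased gene rose and 1 fell. Bile acid genes (25 members), heat shock proteins (16), circadian clock genes (19), cell cycle genes (24) and oxidative phosphorylation genes (26) had 0 members called over all genes and adjusted over the list alone, and list adjusted p values of 0.490, 0.762, 0.777, 0.338 and 0.404.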
